A study of Mus musculus with 36 samples.

How the data were processed

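High-throughput genome-wide translocation sequencing (HTGTS) maps the partner ends that join a chosen bait end. Here the bait was the coding end of JH4 in v-Abl transformed mouse pro-B cell lines, and 36 libraries in 10 groups were read. Every line came from 1 parental line in which 1 heavy chain allele could not recombine and lacked the proximal VH genes. The other allele carried a DJH join of DFL16.1 to JH4, and this allele was altered in the mutant lines. Per the labels, cells were held in G1 with STI-571, an Abl kinase inhibitor, for 4 days. The protocol gives 3 mM STI-571. In a second field 3 libraries carry another entry (4 mM, 5 mM and 6 mM), a conflict that was left open. They are all the libraries of the group IGCR1del_VH5-1-CBEins. If these entries hold, dose and group cannot be told apart in comparisons with that group. Groups and replicate numbers came from the sample titles. The labels do not say that the replicates of a group were separate cultures, so p-values measure only the spread between these libraries, which can be technical.

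The deposited files hold junction records, 1 per sequenced junction, a unit other than counts or normalised values, with the bait end, the prey position and strand, the inserted bases, the read sequence and filter marks. The submitters' processing notes name Bowtie2 and the mouse build mm9, in which all coordinates are given. The files hold 9341310 records with an aligned prey end, from 118328 to 557422 per library, and 99.96% lie on chromosome 12. VH junctions numbered 3154 to 19329 per library in the 5 groups without an Intergenic or IGCR1 deletion, and 100646 to 362725 in the 5 groups with one. The share of VH junctions had a 95% Wilson interval that reached 0.028 to 0.234 percentage points to either side. A count of 0 in a library allows a level of up to 3 junctions over its total, which is 0.538 to 2.54 per 100000. The reads carry no molecular identifiers, so intervals and floors cover counting error only. The duplicate mark is set on 98.9% to 99.9% of records in 32 libraries and on none in the other 4 libraries, which are 1 IGCR1del and 3 IGCR1del_VH5-1-CBEins libraries. All records were therefore counted, whatever their marks. The read names show 15 sequencing runs.

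VH segments were defined without regard to group. Prey positions pooled over all libraries and lying within 200 bp of each other gave 388 clusters. Clusters whose translated reads carried the framework 3 end of a VH gene gave 96 segments. The translation rule and the table of family motifs were revised after the reads had been seen. No mm9 genome or annotation was used here, so reads could not be aligned to gene sequences as planned. Instead 8 segments were named by family, order and spacing, to within 100 bp, against the gene table of assembly GRCm38.p6, whose coordinates are not printed. These 8 are Ighv5-1, Ighv5-2 (the gene called VH81X), Ighv2-2, Ighv5-4, Ighv2-3, Ighv5-6, Ighv2-4 and Ighv5-9. Any other segment is called by its read family and its most used mm9 position on chromosome 12. The lists were the 3 targeted proximal segments (Ighv5-1, Ighv5-2 and Ighv2-2), 33 other proximal segments (V5 and V2 families), 27 middle segments, 31 distal segments (V1 and V8 families) and 2 segments with no family call.

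Junctions per segment were compared with limma 3.58.1 (voom weights, eBayes) in R 4.3.3, with all junctions of a library as its size. One coefficient per group was fitted over all 36 libraries with 26 residual degrees of freedom. Of the 96 segments, 41 had at least 10 junctions in at least 3 libraries and were tested, and p-values were adjusted by Benjamini-Hochberg over these 41 in each comparison, two-sided, with a threshold of 0.05. Of the 41, 3 were targeted, 25 other proximal, 5 middle and 7 distal. There were 10 comparisons of groups and 3 tests of whether an effect differed between backgrounds. Levels are junctions per 100000 junctions, as mean ± SD over libraries. Total VH level, shares of VH groups and region classes were compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment in each family. The smallest p these tests allow is 0.1 for 3 against 3 libraries, 0.0286 for 3 against 4 and 0.0179 for 3 against 5. After adjustment a value passes only if nearly all comparisons of unequal group sizes in its family reach these p together, so a value short of the threshold does not show that groups were alike. Tests, lists and alternatives were fixed before the data were examined, except those named as chosen later.

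Segments named in the text follow a rule fixed at the same time. In each comparison it took the 3 targeted segments, the next 8 tested segments in order from the DH side, the 10 largest changes past the threshold whose libraries did not overlap, and the 5 tested segments with the highest mean level. Other segments are named as members of short lists and were chosen after their values were seen. A fold is the one fitted by limma on the log2 scale and can differ from the ratio of the mean levels printed with it, most where junctions are few. For 1 to 3 junctions the ratio of pooled counts is given with an exact counting interval. Where all libraries of a group had 0 junctions, a fold was computed against the floor of 3 junctions over the group and is a lower bound. On simulated data made for VH81X-CBEdel against WT over 41 segments, with 20 simulations, 5% of 2-fold changes and 46.5% of 4-fold changes were found. Among simulated segments at a level of at least 10 per 100000 these shares were 8.33% and 71.4%.

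Alternatives were VH junctions as the denominator, no filter on low counts, limma on log2 levels without weights, the compared groups fitted alone, identical joins counted once, marked records left out, the main orientation alone, the replicate number as a block, and each library left out in turn. For the total level the mean of log2 levels was also tried. Counting joins or fragments once, and leaving marked records out, applied to all records, so the DJH join and the library size shrank as well. Distinct joins also grew less than junctions: WT replicate 1 had 733 among 3955 VH junctions, and Intergenic-del replicate 1 had 2578 among 101173. A smaller change in these settings therefore does not show that repeated reads made up the rest. Chosen after the data were seen were the sequencing run as a term (12 residual degrees of freedom) or as a random block, identical fragments counted once, libraries with 1 join above 50% of their VH junctions left out, and the IGCR1del_VH5-1-CBEins libraries summed to 1. These last libraries stood closer together than other replicates. The chi-square per degree of freedom between pairs of them, over joins, was 1.25 to 1.78, against 4.41 to 45.3 in the other IGCR1del groups, and they still differed beyond sampling noise (largest p 2.9e-04), so they were kept as 3. Records were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and Biopython 1.88, and figures were drawn with matplotlib 3.10.9.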

Results

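VH to DJH joining was read from the JH4 bait in 36 libraries of v-Abl pro-B lines. The groups were WT (3 libraries), a deletion of the CTCF-binding element (CBE) beside VH81X (VH81X-CBEdel, 3), an inversion of that element (VH81X-CBEinv, 4), a scrambled CBE at Ighv2-2 (VH2-2-CBEscr, 4) and a CBE made at Ighv5-1 (VH5-1-CBEins, 4). CBEs are sites bound by CTCF, a protein that anchors chromatin loops. The other groups carried a deletion of the interval between DH and VH (Intergenic-del, 3), or of IGCR1, the control region within that interval (IGCR1del, 3), alone or with a CBE change: Intergenic-del_VH81X-CBEdel (5), IGCR1del_VH81X-CBEdel (4) and IGCR1del_VH5-1-CBEins (3). Libraries held 118328 to 557422 junctions. On chromosome 12 (mm9) the DJH join lay at 114734565. Ighv5-1 (114830684 to 114830942) was the first VH segment, followed by Ighv5-2, which is VH81X (114836298 to 114837000), Ighv2-2 (114846110 to 114846464), Ighv5-4 (114854985 to 114855735), Ighv2-3 (114869095 to 114869426) and Ighv5-6 (114883367 to 114883730). All levels below are junctions per 100000 junctions, as mean ± SD over the libraries of a group.

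**Figure D1:**
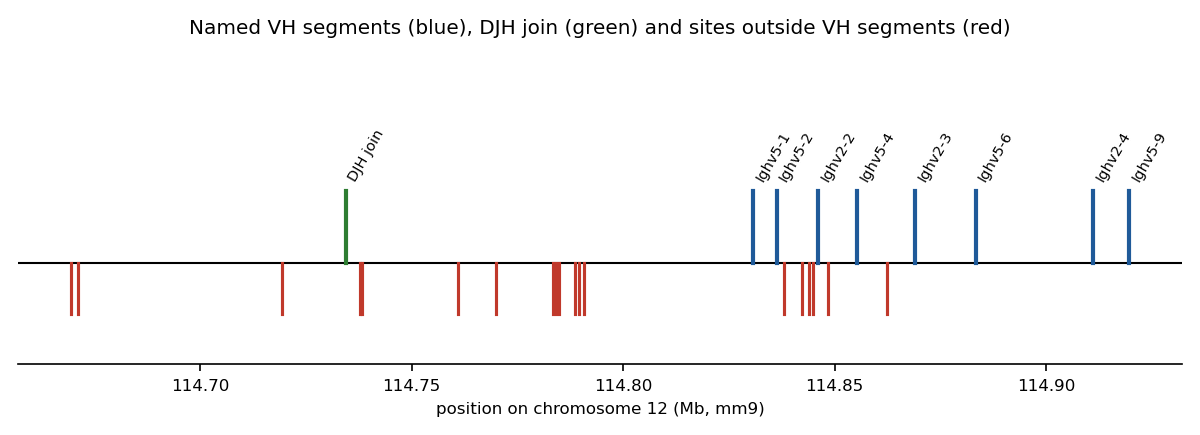
Positions on chromosome 12 (Mb, mm9) of the DJH join (green), the 8 named VH segments (blue, most used junction position) and recurrent sites outside VH segments (red). Ighv5-1, Ighv5-2 and Ighv2-2 are the VH segments nearest to the DJH join.

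In WT, VH segments took 2729 ± 482 of 100000 junctions (n = 3), and the pre-existing DJH join took most of the rest. Ighv5-2 led with 1232 ± 199, followed by Ighv2-2 with 623 ± 154, Ighv5-4 with 292 ± 54.7 and Ighv2-3 with 179 ± 21.3. Ighv5-1, the VH segment nearest to the DJH join, took 67.1 ± 7.64. The targeted proximal segments held 70.4% ± 1.96 of VH junctions, other proximal segments 25.6% ± 1.17, middle segments 1.60% ± 0.466042 and distal segments 2.36% ± 0.7102. The VH total was 2039.5 ± 591 in VH81X-CBEdel, 1507 ± 631 in VH81X-CBEinv (n = 4), 2419 ± 1715 in VH2-2-CBEscr (n = 4) and 2857 ± 765 in VH5-1-CBEins (n = 4). In VH81X-CBEinv and VH2-2-CBEscr the libraries of runs 13 and 14 had lower totals (970 to 974 and 917 to 961) than the others (1887 to 2197 and 3717 to 4079), as had those of run 8 in VH5-1-CBEins (1993 to 2433 against 3468 to 3533). All VH81X-CBEdel libraries came from runs 13 and 14. Single libraries of these 5 groups gave between 0.917% and 4.08% VH junctions, and the 18 libraries of the 5 deletion groups between 70.3% and 95.5%. Of the 4 groups with a CBE change alone, VH81X-CBEinv had the VH total farthest from WT (0.552 times, exact permutation p = 0.0571, adjusted p = 0.25), and none passed.

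**Figure D2:**
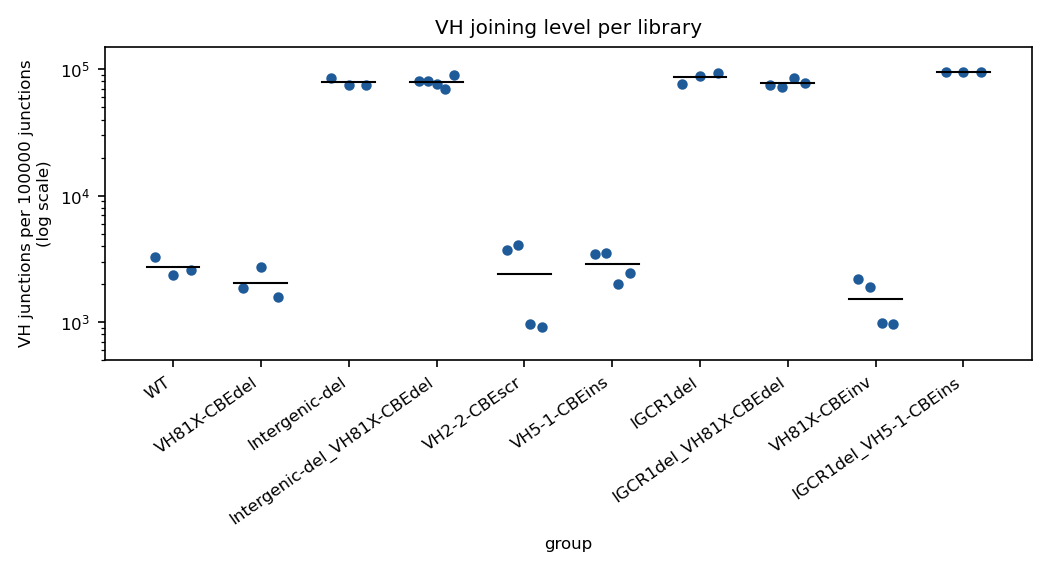
VH junctions per 100000 junctions (log scale) in each library (points) by group, with the group mean (bar). The 18 libraries with an Intergenic or IGCR1 deletion lie at or above 70.3% of junctions, and the other 18 at or below 4.08%.

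The first question was what the CBE beside VH81X does for this segment on an otherwise unaltered allele. Without it, Ighv5-2 fell 119-fold, from 1232 ± 199 in WT (n = 3) to 10.5 ± 3.63 in VH81X-CBEdel (n = 3; log2 change -6.89, SE 0.69, limma adjusted p = 6.3e-12), in 3 of 3 libraries. No other tested segment passed the threshold. Its upstream neighbour Ighv2-2 stood at 1056 ± 311 against 623 ± 154 (1.68-fold, adjusted p = 0.885), Ighv5-4 at 346 ± 112 against 292 ± 54.7, and Ighv5-1, on the DH side, at 44.9 ± 11.6 against 67.1 ± 7.64. All 25 other proximal, 5 middle and 7 distal segments stayed short of the threshold, also when adjusted over the list alone. With VH junctions as the denominator the median of all segments moved up by 0.44 (log2) and Ighv2-2 rose (log2 change 1.19), as it did with identical fragments counted once (0.78), with adjusted p between 1.6e-04 and 0.994 over all alternatives. The share of other proximal segments was 41.3% ± 0.956 against 25.6% ± 1.17 of VH junctions, with no overlap between libraries (exact permutation p = 0.1, the smallest possible for 3 against 3, adjusted p = 0.154). Loss of Ighv5-2, the leading VH segment in WT, by itself raises the share of every other VH segment, Ighv2-2 included. Such shares therefore do not show that other segments gained. No run held libraries of both groups: WT came from runs 2, 3 and 7 and VH81X-CBEdel from runs 13 and 14. With the run as a term, Ighv2-2 (log2 change 1.15), Ighv5-4 (1.11) and Ighv5-1 (0.24) stood higher without passing. The Ighv5-2 change was -6.53 with that term. It was smaller with identical joins counted once (-3.55), identical fragments counted once (-5.57) or marked records left out (-3.36), and its adjusted p was at most 3.8e-09 over all alternatives.

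Turning the element around instead of deleting it asked whether its orientation matters. Ighv5-2 kept more use than after deletion: 363 ± 138 in VH81X-CBEinv (n = 4), which was 33.3-fold above VH81X-CBEdel (log2 change 5.06, SE 0.68, adjusted p = 4.8e-08) and 3.56-fold below WT (-1.83, SE 0.48, adjusted p = 0.00185). Counting identical joins once made these changes 3.01 and -0.54, and leaving marked records out made them 2.84 and -0.53, with adjusted p of at most 9.2e-06 and 0.0276 over all alternatives. Ighv2-2 (524 ± 180), Ighv5-4 (285 ± 166) and Ighv5-1 (34.8 ± 26.1) did not pass against WT. Segments farther away fell against WT: 6 of 7 distal segments (6 when adjusted over the list alone), 3 of 5 middle segments (4 over the list alone) and 10 of 25 other proximal segments (10 over the list alone), and none rose. V5-family_115103579 fell to 0.0721 ± 0.144 from 6.44 ± 0.879, with 1 junction left (WT 83.4 times higher by pooled counts, 95% counting interval 13.9 to 3398). V1-family_116619541, of the distal V1 family, fell to 0.221 ± 0.278 from 8.09 ± 0.749, with 3 junctions left (35.9 times, 11.4 to 181). V11-family_115623228 fell to 1.46 ± 2.18 from 11.9 ± 4.83 (8.13 times between the means, fitted log2 change -4.21), and without VH81X-CBEinv replicate 3, which stood at 4.61, its level was 0.410 (fitted change -5.02), while without replicate 2 the fitted change was -3.25. Over all alternatives this change was smallest with marked records left out, where the call remained. V5-family_115402889 had no junction in the 4 VH81X-CBEinv libraries, at least 3.21-fold below WT. Among the middle segments, V7-family_115470145 (fitted log2 change -3.09) lost its call without VH81X-CBEinv replicate 2 (-2.34). After Ighv5-2, the nearest segment that fell was V5-family_114998634 (3.84 ± 1.43 against 21.6 ± 7.17). This call ended without WT replicate 1 (log2 change -2.24), with VH junctions as the denominator, with identical joins counted once, with marked records left out and with a run term.

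In numbers, 20 of 41 segments passed for VH81X-CBEinv against WT, all lower, and 20 against VH81X-CBEdel, 1 higher and 19 lower. Against VH81X-CBEdel the lower segments were again 6 of 7 distal, 3 of 5 middle and 9 of 25 other proximal segments, with the same counts when adjusted over the list alone. Ighv2-2 was 2.06-fold lower there (log2 change -1.04, SE 0.42, adjusted p = 0.0346). This Ighv2-2 call ended without VH81X-CBEdel replicate 1 (-1.09) or 2 (-0.83), without VH81X-CBEinv replicate 3 (-0.89) or 4 (-0.93) and with VH junctions as the denominator (-0.56). It ended too with identical joins counted once (-0.25), marked records left out (-0.14), a run term (-1.27), no low-count filter or the groups compared alone, with adjusted p between 0.00193 and 0.795 over all alternatives. With VH junctions as the denominator the median moved up by 0.99 against WT and by 0.55 against VH81X-CBEdel, and 9 segments remained lower than WT, of which 3 were distal, 1 middle and 4 other proximal. Identical joins counted once left 8 lower than WT and 1 higher. VH81X-CBEinv and WT shared run 3, with 1 library each: there the total differed by -0.10 (log2), Ighv5-2 by -1.16 and Ighv2-2 by 0.63. Against VH81X-CBEdel, the total differed by -1.14 in run 13 and -0.92 in run 14, Ighv5-2 by 4.58 and 4.56, and Ighv2-2 by -1.49 and -1.40.

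Deleting the interval between DH and VH asked how VH segments fare when they are brought next to the DJH join. VH joining took 78678 ± 5919.7 of 100000 junctions (n = 3), 28.8 times the WT total (exact permutation p = 0.1, the smallest possible, adjusted p = 0.25). Ighv5-2 rose 37.7-fold to 45867 ± 5612 (log2 change 5.24, SE 0.46, adjusted p = 4.9e-14) and Ighv2-2 rose 37.9-fold to 23396 ± 5403. Ighv5-4 rose 23.97-fold to 6977 ± 1491 and Ighv2-3 rose 10.8-fold to 1917 ± 336, while Ighv5-6 did not pass (234 ± 62.1 against 98.0 ± 33.5, adjusted p = 0.141). Ighv5-1, the VH segment nearest to the DJH join in WT, had 0 junctions in replicates 1 and 3 and 17 in replicate 2. These 17 were 13 distinct joins that were all also seen in libraries of other groups of its run. The sample labels do not give the ends of the deletion, so these counts do not show whether the segment was used less or was no longer there. V5-family_115343914, with no junction in WT, rose to 9.77 ± 4.76, at least 16.03-fold, but in the 3 groups with most Ighv5-2 junctions, of which this is 1, 40.3% of its reads lay within 2 mismatches of Ighv5-2. Among the other segments that rose, this share was 25.7% for V5-family_115103579 and 13.5% for V5-family_115120458. Here and below, only reads with at least 100 prey bases were compared, over 80 bases. Of the lists, 11 of 25 other proximal segments rose on all junctions (over the list alone 11 rose and 1 fell), but 21 of them fell with VH junctions as the denominator. Distal segments fell in 2 of 7 and middle segments in 1 of 5, with the same counts when adjusted over the list alone, and in 7 of 7 and 5 of 5 with that denominator.

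In all, 18 of 41 segments passed for Intergenic-del against WT, 14 higher and 4 lower, with Ighv5-1 counted among the lower here and in the alternatives below. With VH junctions as the denominator the median of all segments moved by -4.86 and 35 segments were lower and 0 higher: as a share of VH junctions, Ighv5-2 (log2 change 0.37) and Ighv2-2 (0.37) did not pass and Ighv2-3 fell (-1.43). With identical joins counted once 6 segments were higher and 12 lower, with changes of 1.21 for Ighv5-2 and 1.34 for Ighv2-2, and with identical fragments counted once 4 were higher and 21 lower. Ighv5-9, at 41.2 ± 17.1 against 7.41 ± 4.72 (adjusted p = 0.0203), lost its call without WT replicate 2 (log2 change 2.06) and without Intergenic-del replicate 2 (2.48) or 3 (2.32). V5-family_115180584, at 7.39 against 1.05 in WT, lost its call without WT replicate 1 (2.08). Both calls also ended with identical joins or fragments counted once. In run 2, which held 1 library of each group, the total was higher by 4.71, Ighv5-2 by 5.08, Ighv2-2 by 4.99, Ighv5-4 by 4.63 and Ighv2-3 by 3.17. The interval itself, which took 53.0 ± 10.9 junctions in WT, is absent from this allele, so that its 0 junctions follow from the deletion.

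In that background, removing the VH81X CBE asked whether Ighv5-2, brought closer to the DJH join, still needs it. Ighv5-2 stood at 49876 ± 15237 in Intergenic-del_VH81X-CBEdel (n = 5) against 45867 ± 5612 in Intergenic-del (n = 3; log2 change 0.08, SE 0.38, adjusted p = 0.928). Ighv2-2 (18176 ± 6568 against 23396 ± 5403), Ighv5-4 (8177 ± 4246 against 6977 ± 1491) and Ighv5-6 (484 ± 279 against 234 ± 62.1) did not pass either. With limma 0 of 41 segments passed, 2 had an unadjusted p under 0.05, and limma on log2 levels without weights also gave 0. Adjusted over the list alone, 1 of 7 distal segments fell, V8-family_117276380 (0.0543 ± 0.121 against 1.09 ± 0.535), and none of the 25 other proximal or 5 middle segments passed. That call rests on 1 junction, in replicate 5, against 2, 1 and 2 in the Intergenic-del libraries. These are too few to give the size of a fall. The change of Ighv5-2 on deletion of its CBE was 6.97 (log2, SE 0.78) less negative here than in the WT background (test of the difference, adjusted p = 3.0e-10), the 1 segment that passed this test. This difference was 3.03 with identical joins counted once and 2.84 with marked records left out. Replicates 1 and 5 each held 1 Ighv5-2 join with 78.5% and 56.6% of their VH junctions. Counting identical joins once turned the sign, so that Ighv5-2 fell by 0.52 on the log2 scale and by 0.45 with identical fragments counted once, with adjusted p between 1.7e-05 and 0.982 over all alternatives. Run 13 held 1 library of each group: Ighv5-2 differed by 0.72 and Ighv2-2 by -0.84.

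Scrambling the CBE of Ighv2-2 asked whether this segment depends on its own element. Ighv2-2 fell 119-fold, from 623 ± 154 in WT (n = 3) to 6.03 ± 4.66 in VH2-2-CBEscr (n = 4; log2 change -6.89, SE 0.60, adjusted p = 4.6e-14), in 4 of 4 libraries. Without replicate 2, which stood at 12.97, the level was 3.72 ± 0.711 (log2 change -7.31). It was the 1 segment of 41 that passed. Ighv5-2, its neighbour on the DH side, stood at 1133 ± 763 (adjusted p = 0.596), Ighv5-4 at 477 ± 358, Ighv2-3 at 314 ± 224 and Ighv5-1 at 74.6 ± 43.6. None of the 25 other proximal, 5 middle or 7 distal segments passed, over all tested segments or adjusted over the list alone. VH totals spread widely in this group, from 917 to 4079, and replicates 3 and 4, of runs 13 and 14, stood lower than replicates 1 and 2. With VH junctions as the denominator the median moved up by 0.52. No run held libraries of both groups. With the run as a term 9 segments passed, 1 higher and 8 lower, and the Ighv2-2 change was -7.01. Smaller changes of Ighv2-2 came with identical joins counted once (-3.83), identical fragments counted once (-6.01) and marked records left out (-3.17), and its adjusted p was at most 2.3e-07 over all alternatives. Without VH2-2-CBEscr replicate 1, 2 segments passed. Marked records left out gave 3 segments, 2 higher and 1 lower.

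Placing a CBE at Ighv5-1 asked the converse. Ighv5-1 rose 23.97-fold, from 67.1 ± 7.64 in WT (n = 3) to 1618 ± 365 in VH5-1-CBEins (n = 4; log2 change 4.58, SE 0.67, adjusted p = 5.2e-07), in 4 of 4 libraries. The segments upstream of it stood lower without passing over all tested segments: Ighv5-2 at 525 ± 157 (2.33-fold, adjusted p = 0.181), Ighv2-2 at 304 ± 91.1 (2.03-fold, adjusted p = 0.221), Ighv5-4 at 138 ± 77.4 and Ighv2-3 at 81.2 ± 25.3. Both Ighv5-2 and Ighv2-2 fell when adjusted over the list alone. Ighv5-2 also passed as a share of VH junctions (log2 change -1.29), and Ighv5-2, Ighv2-2 and Ighv5-4 passed with identical joins counted once and with the groups compared alone. The rise of Ighv5-1 by itself lowers the share of every other segment among VH junctions. The other segment that fell was V5-family_115015512 (0.623 ± 0.305 against 5.44 ± 2.63, 6.57-fold, adjusted p = 0.0394), the 1 of 25 other proximal segments past the threshold in either adjustment. No middle or distal segment passed.

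For VH5-1-CBEins, V5-family_115015512 lost its call without WT replicate 1 (log2 change -2.54) or 3 (-2.45), without VH5-1-CBEins replicate 2 (-2.60), 3 (-2.67) or 4 (-2.70), with identical joins counted once, and with the run as a term, where its sign turned (0.19). That call also ended without the low-count filter, with the replicate number as a block and with the run as a random block. WT and VH5-1-CBEins shared no run. With the run as a term the Ighv5-1 change was 3.53 (SE 1.24, adjusted p = 0.283, the highest over all alternatives, the lowest being 4.8e-12), so that no segment passed. The change was 2.64 with identical joins counted once and 2.47 with marked records left out.

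**Figure D3:**
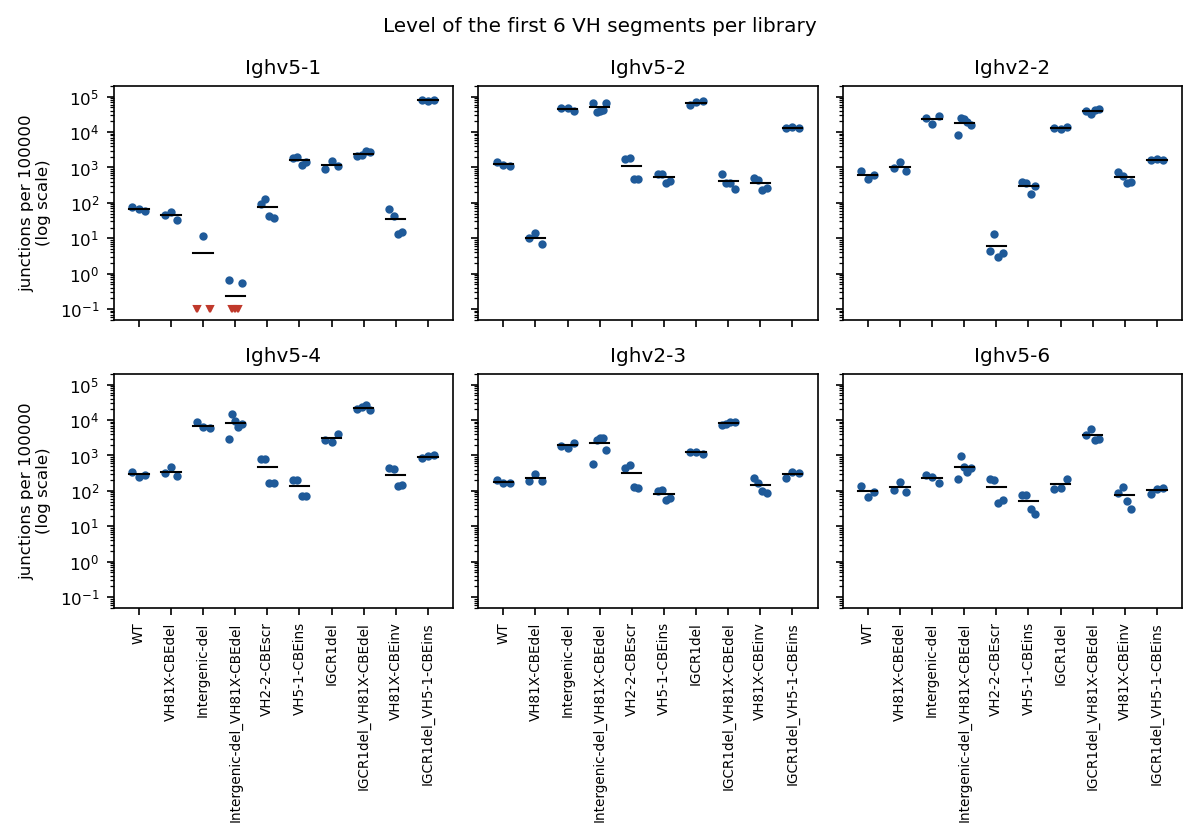
Junctions per 100000 junctions (log scale) for the 6 VH segments nearest to the DJH join, in each library (points) by group with the group mean (bar). Red triangles mark libraries with 0 junctions. Ighv5-2 was at 10.5 in VH81X-CBEdel and 405 in IGCR1del_VH81X-CBEdel, and Ighv5-1 at 78506 in IGCR1del_VH5-1-CBEins.

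Deleting IGCR1 alone asked how VH use changes when this barrier between DH and VH is gone. VH joining took 86315 ± 8739.9 of 100000 junctions (n = 3), 31.6 times WT (exact permutation p = 0.1, the smallest possible, adjusted p = 0.25). Ighv5-2 rose 55.4-fold to 67463 ± 8045 (log2 change 5.79, SE 0.46, adjusted p = 1.8e-15), Ighv2-2 rose 21.5-fold to 13041 ± 722, Ighv5-1 rose 17.2-fold to 1172 ± 302, Ighv5-4 rose 10.3-fold to 3041 ± 814 and Ighv2-3 rose 6.90-fold to 1226 ± 85.9. Ighv5-6 did not pass (151 ± 61.9 against 98.0 ± 33.5). V5-family_115343914, at 0 in WT, rose to 29.4 ± 12.9, at least 48.3-fold, again with 40.3% of its reads close to Ighv5-2. Of 25 other proximal segments 7 rose and 1 fell on all junctions, but 1 rose and 24 fell with VH junctions as the denominator. Distal segments fell in 3 of 7 and middle segments in 2 of 5, and in 7 of 7 and 5 of 5 with that denominator. The counts of these lists were the same when adjusted over the list alone. V1-family_116619541 fell 7.83-fold, to 0.978 ± 0.849.

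For IGCR1del against WT 17 of 41 segments passed, 11 higher and 6 lower. As a share of VH junctions Ighv5-2 rose (log2 change 0.79) while Ighv5-4 (-1.63) and Ighv2-3 (-2.22) fell, and Ighv5-1 (-0.89) and Ighv2-2 (-0.58) stood lower without passing. The median of all segments moved by -5.00, with 2 segments higher and 37 lower. Identical joins counted once gave 5 higher and 14 lower, with 1.496 for Ighv5-2, 1.00 for Ighv2-2, 0.72 for Ighv5-1, 0.50 for Ighv5-4 and 0.13, short of the threshold, for Ighv2-3, and identical fragments counted once gave 4 higher and 24 lower. Repeated records of the DJH join were dropped there too, so these sizes are not on the same scale as those over all junctions. The groups shared no run. With a run term 3 segments were higher and 13 lower: Ighv5-2 changed by 4.10 (SE 0.79) and Ighv2-2 by 3.69 (SE 1.10), and the calls of Ighv5-1 (3.14), Ighv5-4 (1.99) and Ighv2-3 (1.27) ended. Without WT replicate 3 the count was 9. V1-family_116619541 lost its call without IGCR1del replicate 1 (-2.19).

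On the IGCR1-deleted allele, deletion of the VH81X CBE asked where joining goes when the leading segment loses its element. Ighv5-2 fell 169-fold, from 67463 ± 8045 in IGCR1del (n = 3) to 405 ± 168 in IGCR1del_VH81X-CBEdel (n = 4; log2 change -7.40, SE 0.45, adjusted p = 6.5e-20), in 4 of 4 libraries. Segments upstream of it rose. Levels are parts of a fixed total, so the part that Ighv5-2 lost had to go to other junctions. A rise alone therefore does not show that a segment gained beyond its portion of that part. Of the upstream segments named here, Ighv2-2 rose least. Ighv2-2 rose 3.05-fold to 40027 ± 5098, Ighv5-4 rose 7.39-fold to 22093 ± 3338, Ighv2-3 rose 6.56-fold to 8058 ± 806 and Ighv5-6 rose 24.9-fold to 3738 ± 1294. Farther out, Ighv2-4 rose 17.6-fold to 122 ± 84.4 (without IGCR1del replicate 3 the log2 change was 4.77 instead of 4.14) and Ighv5-9 rose 26.7-fold to 506 ± 161. Ighv5-1, on the DH side, stood at 2460 ± 375 against 1172 ± 302 (2.11-fold, adjusted p = 0.0964) and rose when adjusted over the list alone. Of 25 other proximal segments 9 rose and 3 fell, in either adjustment. Those that fell were V5-family_115343914, V5-family_115103579 and V5-family_115015512. In the 3 groups with most Ighv5-2 junctions, IGCR1del among them, 40.3%, 25.7% and 0.776% of their reads lay within 2 mismatches of Ighv5-2, which fell too. No middle or distal segment passed.

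In all 14 of 41 segments passed, 10 higher and 4 lower. The VH total was 77795 ± 5294, 0.901 times IGCR1del, and did not pass (exact permutation p = 0.171). Libraries of the groups overlapped (72607 to 85042 against 76678 to 93727 in IGCR1del). With VH junctions as the denominator the median moved by 0.15, and 13 segments were higher and 4 lower. The Ighv5-2 change was -4.28 with identical joins counted once and -4.09 with marked records left out, with an adjusted p of at most 2.1e-07 over all alternatives. Identical joins counted once gave 1.42 for Ighv5-4, 1.27 for Ighv2-3, 2.59 for Ighv5-6, 2.92 for Ighv2-4 and 2.98 for Ighv5-9. Ighv2-2 was the exception among the named risers, since its change turned to -0.10 with identical joins counted once and to -0.13 with marked records left out. V5-family_114961496, at 237 ± 97.7 against 26.5 ± 16.5, lost its call without IGCR1del replicate 2 (log2 change 2.82). The groups shared no run. With a run term 26 segments were higher and 2 lower, Ighv5-2 changed by -5.67 (SE 0.75), Ighv2-2 by 3.17, Ighv5-4 by 5.56 and Ighv5-6 by 7.26, and V5-family_115103579 turned to 1.18. The rise of upstream segments on loss of the VH81X CBE exceeded that in the WT background for Ighv5-4 by 2.67 (log2, SE 0.80, adjusted p = 0.0155), for Ighv5-6 by 4.27 (SE 0.91, adjusted p = 9.0e-04) and for Ighv5-9 by 4.39 (SE 1.21, adjusted p = 0.00984). These differences were 1.32, 2.33 and 2.50 with identical joins counted once. Levels are parts of a fixed total, so the large part that Ighv5-2 lost in IGCR1del had to go to other junctions. In WT Ighv5-2 took only a small part. The differences therefore do not by themselves show that the element acted otherwise on upstream segments. In the test of differences 6 of 41 segments passed, 5 higher and 1 lower, but for V2-family_115095280 and V5-family_115343914 the effect in the WT background could not be measured, with 0 junctions in WT and 0 and 1 in VH81X-CBEdel. The loss of Ighv5-2 did not differ detectably between backgrounds (-0.51, SE 0.82, adjusted p = 0.878). Without WT replicate 1 only 2 segments passed, and Ighv5-4 (2.55) and Ighv5-9 (3.97) lost their calls.

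Adding the Ighv5-1 CBE to the IGCR1-deleted allele asked how a new element nearest to DH shares joining with those upstream. The STI-571 entries of these libraries differ from those of IGCR1del, so a difference in dose, if real, cannot be told apart from the insertion. Ighv5-1 rose 68.4-fold, from 1172 ± 302 in IGCR1del (n = 3) to 78506 ± 1062 in IGCR1del_VH5-1-CBEins (n = 3; log2 change 6.10, SE 0.53, adjusted p = 6.0e-14). The next segments fell: Ighv5-2 5.08-fold to 13227 ± 307, Ighv2-2 7.81-fold to 1668 ± 31.6, Ighv5-4 3.18-fold to 929 ± 89.1 and Ighv2-3 4.07-fold to 303 ± 64.4. Levels are parts of a fixed total, so the part that Ighv5-1 gained had to come from other junctions. A fall alone therefore does not show that a segment lost more than its portion of that part. Ighv5-6 did not pass (107 ± 20.8 against 151 ± 61.9). The VH total was 94827 ± 564, 1.10 times IGCR1del (exact permutation p = 0.1, adjusted p = 0.25). Of 25 other proximal segments 6 fell, in either adjustment, and no middle segment passed. Among these 6, V5-family_115264679 (log2 change -2.56) lost its call without IGCR1del replicate 2 (-1.88). Of 7 distal segments V1-family_116619541 fell, with no junction left (at least 2.04-fold), and 0 fell when adjusted over the list alone.

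Of 41 segments 11 passed, 1 higher and 10 lower. The median moved by -0.14 with VH junctions as the denominator. Identical joins counted once made the changes smaller, at 2.99 for Ighv5-1, -1.07 for Ighv5-2, -1.37 for Ighv2-2 and -0.67 for Ighv2-3, and ended the Ighv5-4 call (-0.30). Ighv5-4 lost its call without IGCR1del replicate 3 (log2 change -1.47), and with the 3 IGCR1del_VH5-1-CBEins libraries summed to 1 (-1.65), as did Ighv2-3 (-1.97). In run 12, with 1 library of each group, the total differed by 0.03, Ighv5-1 by 6.14, Ighv5-2 by -2.51, Ighv2-2 by -3.05, Ighv5-4 by -2.24 and Ighv2-3 by -2.30. These effects were compared with those of the insertion in the WT background. The gain of Ighv5-1 was not detectably larger (1.51, SE 0.86, adjusted p = 0.4926). The loss of Ighv5-2 was not detectably larger either (-1.13, SE 0.63, adjusted p = 0.4926). For Ighv5-1 this decides nothing, since it already took 82.8% of VH junctions in IGCR1del_VH5-1-CBEins, with little room for a larger gain. For Ighv5-2 it decides nothing either. The large part that Ighv5-1 gained on the IGCR1-deleted allele had to come from other junctions, most of which were Ighv5-2. Over all alternatives the limma adjusted p was 0.0211 to 0.972 for either segment, so each passed in some alternative. The differences there were -0.16 to 2.60 for Ighv5-1 and -1.45 to -0.33 for Ighv5-2. In the main fit 1 segment passed the threshold, V5-family_115343914. It had 0 junctions in WT and 4 in VH5-1-CBEins, so that its effect in the WT background could not be measured and no difference is shown. Without WT replicate 1 or without VH5-1-CBEins replicate 3, 2 segments passed, the latter including Ighv2-2 (-2.16), and adjusted over the list alone Ighv2-2 passed as well (-1.95, SE 0.64).

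Shares of the VH groups did not pass the exact permutation test in any comparison after adjustment, where the smallest adjusted p was 0.154, but with these group sizes the test could hardly be passed. Targeted proximal segments held 88.1% ± 0.990 of VH junctions in Intergenic-del, 94.6% ± 0.701 in IGCR1del and 98.5% ± 0.197 in IGCR1del_VH5-1-CBEins. In IGCR1del_VH81X-CBEdel they held 55.0% ± 4.82, and other proximal segments held 44.9% ± 4.82 against 5.34% ± 0.697 in IGCR1del (exact permutation p = 0.0286, the smallest possible). Loss of Ighv5-2, a targeted segment, by itself raises the share of the other segments there. Middle segments held 0.0789% ± 0.1004 in Intergenic-del, a mean carried by 175 junctions of V3/V12-family_115876813 in replicate 1 (0.0210% without this library), and 0.0131% ± 0.00571 in IGCR1del. Distal segments held 0.0220% ± 0.00532 and 0.0187% ± 0.00906. Junctions in the VH domain outside VH segments were at 68.4 ± 7.11 in IGCR1del_VH81X-CBEdel and 22.0 ± 1.60 in IGCR1del. In VH81X-CBEinv they were at 3.81 ± 1.72 against 13.01 ± 6.49 in WT (exact permutation p = 0.0286, adjusted p = 0.278). Junctions to other chromosomes were at 106 ± 19.4 in IGCR1del, 24.7 ± 8.43 in WT and 24.6 ± 4.35 in IGCR1del_VH81X-CBEdel. No region class passed after adjustment, where the smallest adjusted p was 0.278.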

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

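All tests of explanations and all counts of splits in this part were chosen after the results were seen, as were the bounds they were held against.

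Segments far from DH were lower in VH81X-CBEinv than in WT and VH81X-CBEdel: middle and distal segments together took 17.6 ± 12.4 junctions per 100000 (n = 4), 106 ± 23.3 in WT (n = 3) and 84.4 ± 17.1 in VH81X-CBEdel (n = 3), with 11.4 ± 1.78 in VH81X-CBEinv without replicate 3, which stood at 36.0. Against a difference between sequencing runs, the level was also lower inside shared runs, by a log2 ratio of -2.73 in run 3 (WT), -2.75 in run 13 and -1.35 in run 14 (VH81X-CBEdel), although in run 14 it stood above the VH2-2-CBEscr library (1.02). A lower total VH level of the libraries stays open, since the share of VH junctions differed by -2.63 in run 3 and -1.64 in run 13, but by only -0.43 in run 14. A boundary at 115 Mb was looked at first, and the lists fixed earlier were used for these values. An effect of the inverted element on segments far upstream is a possible explanation that the design names and that these runs, with 1 VH81X-CBEinv library each, could not settle.

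Several V5-family segments rose with IGCR1 deletion and with Intergenic deletion, and V5 is the family of Ighv5-2, which rose most in level. Only reads with at least 100 prey bases were compared with Ighv5-2. Among these, reads shared with Ighv5-2 are argued against for V5-family_115015512 and V5-family_115264679. Only 0.776% and 1.11% of them lay within 2 mismatches of Ighv5-2 in the 3 groups with most Ighv5-2 junctions. Sharing through shorter reads stays open, also for the fall of V5-family_115015512 in IGCR1del_VH81X-CBEdel. For V5-family_115343914 (40.3%), V5-family_115103579 (25.7%) and V5-family_115120458 (13.5%) sharing stays open. In these 3 a rise from reads of Ighv5-2 placed at a related segment could not be told apart from use of the segment itself, and the same holds for the falls of V5-family_115343914 and V5-family_115103579 in IGCR1del_VH81X-CBEdel, where Ighv5-2 fell. A rise in use with the other proximal segments is the open biological explanation and was not tested.

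In Intergenic-del_VH81X-CBEdel 1 Ighv5-2 join took 78.5% of the VH junctions of replicate 1 (284692 junctions) and 56.6% of replicate 5 (188056). Amplification of few DNA fragments may account for this, in which case the join would have few distinct prey ends. The effective number of prey ends over that of the next joins of any segment was 0.733 in replicate 1 and 0.42 in replicate 5, but against the next joins of Ighv5-2, a comparison added after the first values were seen, it was 0.997 and 1.045. The explanation therefore stays open, as does the outgrowth of a cell that carried the join, which was not tested.

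In 70 groups of values tested for a library far from the others 2 stood apart, where chance gives about 1 in 20. The level of Ighv2-2 in VH2-2-CBEscr replicate 2 was 12.97 per 100000, against 2.96 to 4.38 in the others. The distal share in VH2-2-CBEscr replicate 4 was 1.10%, against 1.74% to 1.86%.

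In limma's test of whether the effect of a CBE change differed between backgrounds, 8 values passed the threshold. With VH81X-CBEdel in Intergenic-del against WT, Ighv5-2 differed by 6.97 (log2; 2.84 with marked records left out). With VH81X-CBEdel in IGCR1del against WT, Ighv5-4 differed by 2.67, Ighv5-6 by 4.27, Ighv5-9 by 4.39 and Ighv2-3 by 2.41. The large part of all junctions that Ighv5-2 lost in IGCR1del had to go to other junctions. These differences therefore do not by themselves show another effect of the element on upstream segments. The values for V2-family_115095280 (3.30) and V5-family_115343914 (-3.67) show no difference between backgrounds, since WT had 0 junctions of either and VH81X-CBEdel 0 and 1, so that they restate the change within IGCR1del, where 40.3% of the reads of V5-family_115343914 were also close to Ighv5-2. Without WT replicate 1 the calls of Ighv5-4 (2.55), Ighv5-9 (3.97), Ighv2-3 (2.32) and V2-family_115095280 (3.09) ended, and that of V2-family_115095280 also without IGCR1del replicate 1 (3.03) or 2 (3.01). The Ighv2-3 call ended too without WT replicate 2 (2.45) or 3 (2.45), VH81X-CBEdel replicate 1 (2.31) or 3 (2.28), IGCR1del replicate 1 (2.42), 2 (2.44) or 3 (2.35), and IGCR1del_VH81X-CBEdel replicate 3 (2.37) or 4 (2.36). With VH5-1-CBEins in IGCR1del against WT, the value of V5-family_115343914 was -4.40, again with too few junctions in the WT background (0 in WT, 4 in VH5-1-CBEins) to measure an effect there.

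Outside the comparisons, VH junctions in the reverse orientation reached 3331 per 100000 (3330.8) in Intergenic-del replicate 2, where 4907 of 5022 such junctions were 1 Ighv5-2 join at 114836376, against 159 in the next library. A site between DH and VH, 49.0 kb from the DJH join at 114783433 to 114783762 (mm9), took 13.7 ± 0.706 junctions per 100000 in IGCR1del, 173 ± 265 (172.95) in IGCR1del_VH81X-CBEdel and 7.07 ± 4.19 in IGCR1del_VH5-1-CBEins and none in WT, at least 22.4-fold, 284-fold and 11.6-fold higher. In IGCR1del_VH81X-CBEdel replicate 1 carried this level with 570, and without it the mean was 40.6 ± 12.5, at least 66.6-fold above WT.

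The same libraries were split into groups of the same sizes, with the compared groups fitted alone. No other split gave as many segments for VH81X-CBEinv against WT (20 segments, highest other split 12, 1 of 35 splits as large), VH81X-CBEinv against VH81X-CBEdel (20, 15, 1 of 35), VH5-1-CBEins against WT (7, 1, 1 of 35) and IGCR1del_VH81X-CBEdel against IGCR1del (17, 7, 1 of 35). This is the smallest share that 35 splits allow, and it was not adjusted over the comparisons. Replicates may be technical, so it speaks for these libraries only, and chance between cell lines is not excluded. The splits take no account of the sequencing run, and the last 2 pairs of groups shared no run, so a difference between runs is not excluded by them. For VH5-1-CBEins the number was 2 with all groups fitted together, 1 with the run as a random block and 0 with it as a term, and for IGCR1del_VH81X-CBEdel these were 14, 15 and 28. For the effect of VH81X-CBEdel in IGCR1del against WT (10, 15, 4 of 100) the split with 15 kept each group whole and exchanged WT with VH81X-CBEdel, so that the number followed the change within IGCR1del and chance stays open for the difference of effects. For Intergenic-del_VH81X-CBEdel against Intergenic-del (0, 2, 56 of 56) the number was 0, so every split is as large and the splits test nothing. As to the number of segments, chance cannot be excluded for VH2-2-CBEscr against WT (1, 19, 10 of 35), for the effect of VH81X-CBEdel in Intergenic-del (1, 1, 10 of 100) or for the effect of VH5-1-CBEins in IGCR1del (4, 14, 6 of 100). These counts do not test single segments: over all alternatives the change of Ighv2-2 in VH2-2-CBEscr kept an adjusted p of at most 2.3e-07, and the Ighv5-2 difference of effects in Intergenic-del one of at most 1.3e-07. The VH2-2-CBEscr split with 19 segments put WT replicate 2 with VH2-2-CBEscr replicates 3 and 4, the 3 libraries with the lowest VH totals of these groups, which points to a structure of the samples whose cause was not tested. For VH81X-CBEdel against WT (1, highest other 0), Intergenic-del against WT (27, 1), IGCR1del against WT (22, 0) and IGCR1del_VH5-1-CBEins against IGCR1del (14, 1), 10 splits are too few for a share under 0.05.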

How the results depend on the processing

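The sequencing run as a term or random block, identical fragments counted once, leaving out libraries with 1 dominant join and summing the IGCR1del_VH5-1-CBEins libraries were chosen after the data were seen. Of the values of named segments, 149 of 184 kept direction and side of the threshold with VH junctions as the denominator, 179 without the low-count filter, 178 without weights, 163 with groups compared alone, 135 of 162 with identical joins counted once, 93 of 114 with marked records left out, 184 of 184 in the main orientation alone, 182 with the replicate number as a block, 161 with the run as a term, 181 with it as a random block, 140 of 169 with identical fragments counted once, 178 without the dominant-join libraries, 22 of 28 with the libraries summed and 1416 of 1467 with each library left out. The 970 alternatives for totals, shares and region classes gave no value past the threshold, which says nothing about stability, since adjusted exact permutation tests at these group sizes could hardly pass. Marked records left out gave no value for IGCR1del_VH5-1-CBEins against IGCR1del or for its difference of effects. Levels under about 10 per 100000 limit what can be found: 46.5% of simulated 4-fold changes were found over all segments and 71.4% above that level.

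Counts past the threshold moved as follows, and the cause was not tested except where stated. With VH junctions as the denominator they were 2 for VH81X-CBEdel, 9 for VH81X-CBEinv, 35 for Intergenic-del and 39 for IGCR1del, each against WT, 2 for the effect of VH81X-CBEdel in Intergenic-del and 3 for the effect of VH5-1-CBEins in IGCR1del. This denominator rose with the VH total itself. Counting joins or fragments once, or leaving marked records out, also changed the library size, since records of the DJH join were dropped too. Without the filter, and so with 96 segments tested, they were 44 for VH81X-CBEinv against WT, 34 against VH81X-CBEdel, 1 for Intergenic-del_VH81X-CBEdel and 1 for VH5-1-CBEins. Without weights the effect of VH5-1-CBEins in IGCR1del gave 2. With groups compared alone VH5-1-CBEins gave 7, the effect of VH81X-CBEdel in IGCR1del 10 and that of VH5-1-CBEins 4. With identical joins counted once VH81X-CBEinv against WT gave 9, Intergenic-del_VH81X-CBEdel 3, VH5-1-CBEins 4 and its effect in IGCR1del 3. With marked records left out, and so with 15 segments tested, VH81X-CBEinv gave 3 against WT and 4 against VH81X-CBEdel, Intergenic-del 11, Intergenic-del_VH81X-CBEdel 3, VH2-2-CBEscr 3, VH5-1-CBEins 5 and IGCR1del 11. With the replicate number as a block VH5-1-CBEins gave 1, and with the run as a random block 1. With the run as a term VH81X-CBEdel gave 2, VH2-2-CBEscr 9, VH5-1-CBEins 0, IGCR1del_VH81X-CBEdel 28, the effect of VH81X-CBEdel in IGCR1del 14 and that of VH5-1-CBEins 0. With identical fragments counted once VH81X-CBEdel gave 2, Intergenic-del_VH81X-CBEdel 3, VH5-1-CBEins 6, IGCR1del 28, the effect of VH81X-CBEdel in Intergenic-del 2 and that of VH5-1-CBEins in IGCR1del 2. Without the dominant-join libraries Intergenic-del_VH81X-CBEdel gave 3 and the effect of VH5-1-CBEins in IGCR1del 2. With the libraries summed, and so with fewer samples, IGCR1del_VH5-1-CBEins gave 6 and its difference of effects 0. With each library left out in turn counts ranged from 1 to 2 for VH2-2-CBEscr and for VH5-1-CBEins, 9 to 19 for IGCR1del (lowest without WT replicate 3), 2 to 6 for the effect of VH81X-CBEdel in IGCR1del (lowest without WT replicate 1) and 1 to 2 for the effect of VH5-1-CBEins in IGCR1del.

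Log2 changes that turned sign with VH junctions as the denominator were, in Intergenic-del against WT, Ighv5-4 (-0.29), Ighv2-3 (-1.43), Ighv5-6 (-3.62), Ighv2-4 (-2.77), Ighv5-9 (-2.29), V5-family_115120458 (-1.47), V5-family_115180584 (-2.03), V5-family_115215891 (-1.60) and unassigned-family_115944977 (-1.77), and in IGCR1del against WT Ighv5-1 (-0.89), Ighv2-2 (-0.58), Ighv5-4 (-1.63), Ighv2-3 (-2.22), Ighv5-6 (-4.38), Ighv2-4 (-2.50) and Ighv5-9 (-3.50). With identical joins counted once they were Ighv5-2 (-0.52) and Ighv2-3 (0.32) in Intergenic-del_VH81X-CBEdel, Ighv5-6 in IGCR1del (-1.13), Ighv2-2 in IGCR1del_VH81X-CBEdel (-0.10) and Ighv5-6 in IGCR1del_VH5-1-CBEins (0.73). With marked records left out they were Ighv5-9 in Intergenic-del (-0.31), Ighv5-2 in Intergenic-del_VH81X-CBEdel (-0.53), Ighv5-6 in IGCR1del (-1.41) and Ighv2-2 in IGCR1del_VH81X-CBEdel (-0.13). With identical fragments counted once they were Ighv5-6 in Intergenic-del (-1.18), Ighv5-2 (-0.45) and Ighv2-3 (0.48) in Intergenic-del_VH81X-CBEdel, Ighv2-3 (-0.21) and Ighv5-6 (-2.12) in IGCR1del and Ighv2-2 in the effect of VH81X-CBEdel in IGCR1del (-0.66). With the run as a term they were V5-family_115015512 in VH5-1-CBEins (0.19) and V5-family_115103579 in IGCR1del_VH81X-CBEdel (1.18).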

Other observations

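Sites outside VH segments, sought after the data were seen, also took junctions from the JH4 bait. A pair of sites close to the DJH join, 3.16 kb and 3.64 kb from it, were used in all 18 libraries of WT, VH81X-CBEdel, VH81X-CBEinv, VH2-2-CBEscr and VH5-1-CBEins, at 13.3 ± 1.73 and 29.8 ± 9.20 junctions per 100000 in WT (n = 3). They had 0 junctions in the 18 libraries with an Intergenic or IGCR1 deletion. The sites lie in the interval between DH and VH that the Intergenic deletion removes, and the sample labels give no ends for the IGCR1 deletion, so these 0 counts show no lower use of sites that were still present.

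Among and beside the first VH segments, other sites were used more in IGCR1del_VH81X-CBEdel (n = 4) than in IGCR1del (n = 3) in level, with no test made. The site 108 kb from the DJH join, between Ighv5-2 and Ighv2-2, stood at 13.5 ± 2.27 against 1.21 and at 0 in WT (at least 22.2-fold). The site at 128 kb, between Ighv5-4 and Ighv2-3, stood at 11.2 ± 5.21 against 0.254 and at 0 in WT (at least 18.4-fold), and the site at 114 kb, upstream of Ighv2-2, at 6.61 ± 2.40 against 1.22 and at 0 in WT (at least 10.8-fold). Within the interval between DH and VH, a site at 114784088 stood at 19.9 ± 5.95 against 4.65 in IGCR1del and 1.24 in WT. On the other side of the DJH join, near the bait, a site at 114669442 stood at 24.7 ± 6.16 in IGCR1del, 11.8 ± 2.23 in IGCR1del_VH5-1-CBEins, 3.74 ± 1.92 in IGCR1del_VH81X-CBEdel and 1.00 in WT.

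The 17 Ighv5-1 junctions of Intergenic-del replicate 2 were 13 distinct joins, and all 13 were also seen in libraries of other groups of the same run, which held 9508 Ighv5-1 junctions. Replicates 1 and 3 had 0. In Intergenic-del_VH81X-CBEdel, 3 junctions in replicate 1 were 3 such joins, and 2 in replicate 5 were joins not seen in other groups of the run.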
